A study of Mus musculus with 12 samples.

How the data were processed

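Hypothalamic RNA of male C57BL/6J mice with diet-induced obesity was measured on 12 one-colour Affymetrix arrays, 1 array per sample, with 4 arrays each for DMSO (the vehicle), celastrol and withaferin A. Per the labels, the arrays of a group are biological replicates, biotin-labelled cDNA was hybridised, and the authors processed the signals with RMA. The deposited values are therefore log2 signal values of 35556 probe sets, already brought to a common scale across arrays; the labels give no software version for RMA. The values ran from 2.64 to 15.08, and the array medians from 6.89 to 6.98. Correlations between arrays over all probe sets lay between 0.981 and 0.994, and 0 pairs of arrays held identical values. No counts underlie array values, so the number of arrays limits the precision.

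Probe sets were paired with genes through a probe table for the array. Of the 35556 probe sets, 21789 had exactly 1 gene symbol, 1621 had several and 12146 had none; 21698 of the 21789 were matched by gene identifier to a mouse gene table, and 0 symbols were updated. The 21789 probe sets stood for 19938 genes. For the 999 genes with several probe sets, the one with the highest mean over the 12 arrays was used. Genes with a mean below the 25th percentile, a log2 signal of 5.81, were left out as dim, and 14953 genes were tested.

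Group means were fitted to all 12 arrays with limma 3.58.1 (lmFit and eBayes, R 4.3.3), and the 3 groups were compared pairwise with two-sided moderated tests. Adjusted p-values are Benjamini-Hochberg values over the 14953 genes of a comparison, with a threshold of 0.05. Errors given with log2 fold changes are standard errors (SE) from this fit, with n = 4 arrays per group; the pooled spread had 9 residual degrees of freedom and a prior of 4.44. The 2 compounds were compared with each other directly, since a gene past the threshold for one and not for the other is not shown to differ between them.

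A set of 29 gene lists covered feeding neuropeptides, signalling and stress responses, glucocorticoid-responsive genes, the clock, metabolism, cell types of the brain, and tissues next to the hypothalamus. Each list was tested against the other genes with limma's camera, with a preset correlation between genes of 0.01, and adjusted over the 29 lists of a comparison. The tests were repeated with a correlation estimated for each list (statmod 1.5.0) and with fry, which tests whether the members of a list move on balance in one direction. A count called "adjusted over the list alone" comes from adjusting p over the members of that list.

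The groups, tests, lists and the rule for naming genes were fixed before the data were examined. The rule took, in each comparison, the 10 genes that rose most and the 10 that fell most among those past the threshold, passing over predicted genes, small RNAs, secretoglobins and the olfactory, vomeronasal and taste receptors. Where fewer than 10 passed, it took the 10 genes of any kind with the smallest p. It also took 10 fixed genes in both comparisons with DMSO, of which 8 had a value, and up to 4 members with the smallest p from each list described.

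The steps were tested on simulated data of the same size, with independent errors and 200 changed genes per treated group in each of 5 runs. For celastrol versus DMSO, 93.3% of genes changed by a log2 value of 0.5 and 100% of those changed by 1 were recovered, and 4.78% of calls were false. For withaferin A versus DMSO the values were 92.2%, 99.7% and 5.35%, and for withaferin A versus celastrol 94.7%, 100% and 4.74%. A simulated list of 23 genes shifted by 0.5 was called in 5 of 5 runs, while 0 of 140 unshifted lists were called, with either correlation. Since the errors were independent between genes, these runs cannot show how often lists of correlated genes are called falsely. The recovery of single genes likewise holds only for such errors and that number of changed genes.

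The alternatives tried were no filter on dim genes, a filter at the 50th percentile, every probe set without a filter, a renewed quantile normalization, centring of each array on its median, an intensity trend with a robust prior, array weights, fits to the 8 arrays of 2 groups, a replicate block, an adjusted p threshold of 0.10, a minimum of 1.2-fold, and leaving out each array in turn. Chosen after the data were seen were marker scores of thalamus, or of pituitary and thalamus, as covariates, the omission of celastrol replicate 2 with withaferin A replicate 1, and lists without shared members. For the agreement of the compounds, the controls were also split 2 and 2. Probe sets with no symbol or several symbols were left out of the tests per gene because their signal cannot be given to 1 gene. Plots were drawn with matplotlib 3.10.9.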

Results

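The series profiled the hypothalamus of mice with diet-induced obesity after celastrol or withaferin A, plant compounds known to reduce food intake and body weight in obese mice. Male C57BL/6J mice were fed a diet with 45% fat for 20 weeks from 3 weeks of age and were 23 weeks old. After 4 days of daily intraperitoneal DMSO, they received DMSO, celastrol at 100 µg/kg or withaferin A at 2 mg/kg daily for 4 days. Each group had 4 biological replicates, for 12 arrays in total. The log2 signal of 14953 genes was compared between groups.

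Celastrol was compared with DMSO to find the hypothalamic genes whose expression differed after treatment. Celastrol raised the transcripts of Lcn2 (probe set 10481627), a secreted lipocalin of the acute phase response, by a log2 value of 3.45 ± 0.51 (SE, n = 4 per group), or 10.9-fold. The glucocorticoid-induced genes Zbtb16 and Fkbp5 rose 3.58-fold and 2.31-fold, with log2 values of 1.84 ± 0.30 and 1.21 ± 0.23. Each SE pools the spread of all 3 groups, which can differ. The SD of Zbtb16 was 0.13 with DMSO, 0.21 with celastrol and 0.87 with withaferin A, and that of Lcn2 was 0.42, 0.63 and 1.32. Osmr, the oncostatin M receptor, rose by 1.26 ± 0.21, and Ch25h, which makes 25-hydroxycholesterol, by 1.43 ± 0.20. Opalin, a myelin protein gene of oligodendrocytes, fell 2.00-fold (SE of the log2 value 0.18), and the clock output gene Dbp fell by 0.65 ± 0.07.

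In limma's test 115 of the 14953 genes passed the threshold, of which 68 rose and 47 fell. The adjusted p was 0.0141 for Lcn2, 0.0184 for Zbtb16, 0.0369 for Fkbp5, 0.0191 for Osmr, 0.0141 for Ch25h, 0.0229 for Opalin and 0.00463 for Dbp. Other genes that rose most were Plin4 by 1.65 ± 0.33, Xdh by 1.43 ± 0.23, Lrg1 by 1.30 ± 0.16, Sgk3 by 1.30 ± 0.28 and Pdk4 by 1.13 ± 0.15, with adjusted p from 0.00739 to 0.0488. Plin4 codes for a lipid droplet protein, and Pdk4 for a kinase that limits glucose oxidation. Among genes that fell were Cd180 by 0.92 ± 0.16, Serpinb1a by 0.79 ± 0.15, Plekho2 by 0.70 ± 0.10, the iron exporter gene Slc40a1 by 0.63 ± 0.10, P2ry13 by 0.56 ± 0.12, Tek by 0.55 ± 0.11, Adgre5 by 0.53 ± 0.10 and Fndc9 by 0.51 ± 0.09. Their adjusted p ran from 0.0141 to 0.045. The count was 20 without DMSO replicate 1, 6 without DMSO replicate 2, 62 without DMSO replicate 3, 32 without DMSO replicate 4, 67, 17 and 12 without celastrol replicates 1, 2 and 3, and 207 without withaferin A replicate 1. Of the 20 genes that rose or fell most, Dbp kept its call in the 24 alternatives in which it was followed and Lrg1 in 23. Both lost it with pituitary and thalamus marker scores as covariates (0 genes in all). Single genes were not followed with every probe set tested, where 5 probe sets passed. The other 18 genes lost their call at least without DMSO replicate 2 (adjusted p up to 0.149 over the alternatives, for Sgk3). Lcn2 lost its call without DMSO replicate 2 (adjusted p = 0.0682), celastrol replicate 2 (0.0524) or celastrol replicate 3 (0.051).

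**Figure D1:**
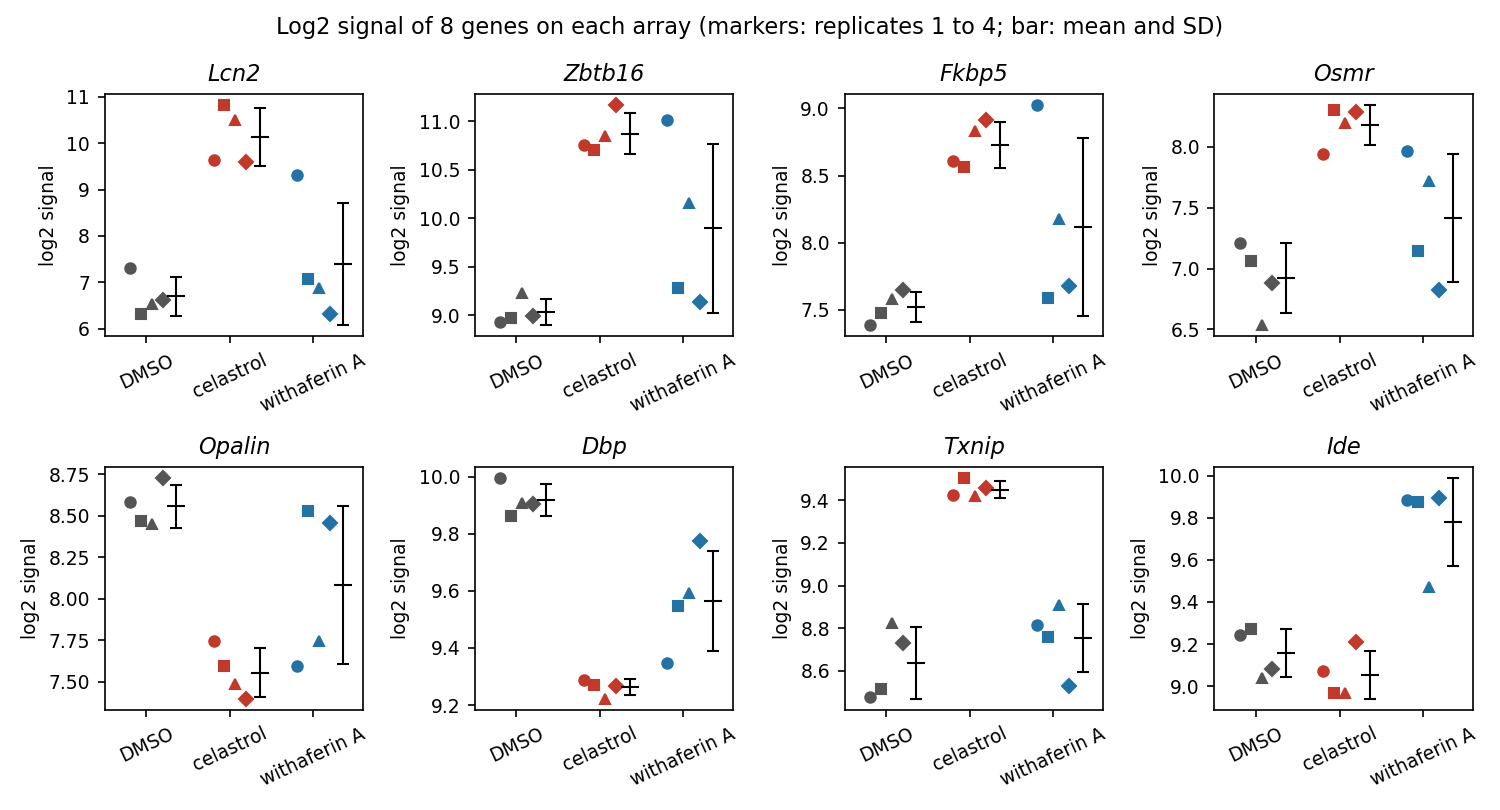
Log2 signal (vertical axes) of 8 genes on each of the 12 arrays by group, with circles, squares, triangles and diamonds for replicates 1 to 4 and bars for the group mean and SD (n = 4). Lcn2 lay between 9.59 and 10.83 on the celastrol arrays and between 6.32 and 7.30 on the DMSO arrays, while the withaferin A arrays ran from 6.32 to 9.31.

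Of the 29 gene lists camera called 12 after celastrol, 5 higher and 7 lower; 2 held with an estimated correlation, and fry called 4. The glucocorticoid-responsive list had the largest median. Of its 23 tested members 15 rose, 0 fell and 8 did not pass, and 21 rose when adjusted over the list alone. The median change was 0.73, with Pdk4, Lcn2, Angptl4 (0.63 ± 0.10, adjusted p = 0.0158) and Nfkbia (0.73 ± 0.12, adjusted p = 0.0158) as members with the smallest p. Sgk1, a salt-regulating kinase gene induced by corticosteroids, rose by 0.86 ± 0.17 (adjusted p = 0.0381), while Per1 had a value of 0.09 (adjusted p = 0.797) and Dusp1 of −0.05 (adjusted p = 0.94). The camera adjusted p of the list was 2.26e-37, and adjusted p = 0.0388 with an estimated correlation. The list mean over DMSO was 0.78, 0.91, 0.90 and 0.84 on the 4 celastrol arrays, against −0.07, −0.09, 0.07 and 0.09 on the DMSO arrays. With pituitary and thalamus marker scores as covariates, chosen after the data were seen, with pituitary scores that did not overlap between celastrol and DMSO arrays, the mean change of the list was 0.89 ± 0.24, against 0.86 ± 0.15 without; 0 members and 0 of all genes then passed, and adjusted p = 0.156 with an estimated correlation.

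The list of leptin and cytokine STAT3 targets also rose after celastrol. Of its 27 members 5 rose and 0 fell, namely Lrg1, Lcn2, Ch25h, Osmr and Il6ra (0.32 ± 0.06, adjusted p = 0.0394), and 9 rose adjusted over the list alone. The median was 0.10, the camera adjusted p was 1.72e-10, and adjusted p = 0.00425 with an estimated correlation. Without the members shared with the glucocorticoid-responsive list, 25 remained, with 4 rising and adjusted p = 0.00302 with an estimated correlation; this form was chosen after the data were seen. With pituitary and thalamus marker scores as covariates, the full list had adjusted p = 0.0982 with an estimated correlation. Socs3, a STAT3 target that limits leptin signalling, had a value of 0.29 ± 0.11 (adjusted p = 0.334) and did not pass.

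**Figure D2:**
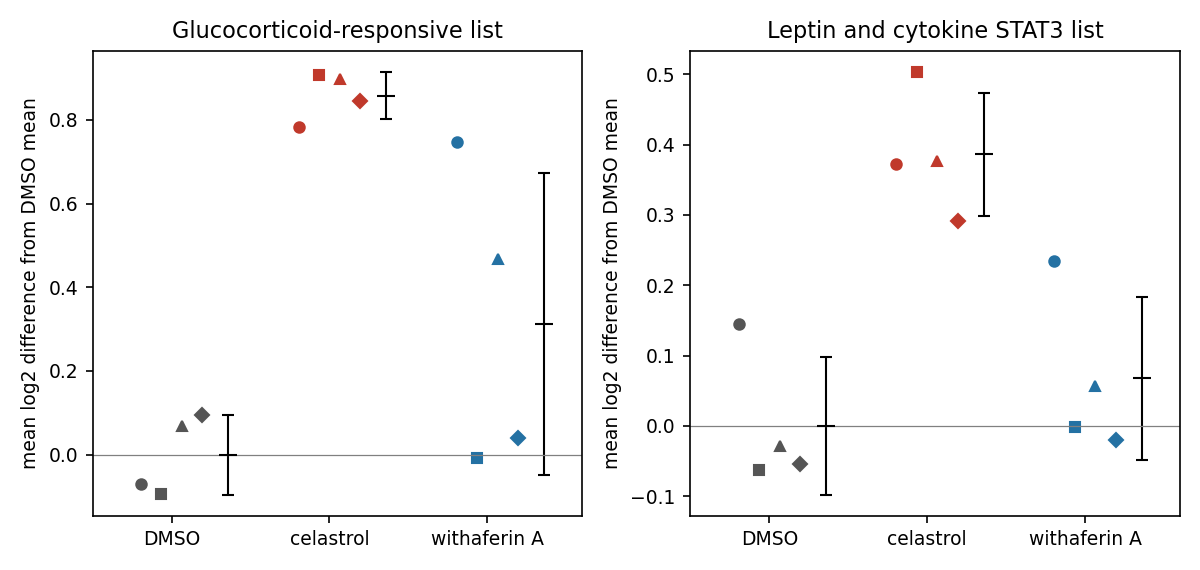
Mean log2 difference from the DMSO mean (vertical axes) over the members of the glucocorticoid-responsive list (23 genes, left) and the STAT3 list (27 genes, right) on each array by group, with circles, squares, triangles and diamonds for replicates 1 to 4 and bars for the group mean and SD (n = 4). On the left the celastrol arrays lay between 0.78 and 0.91, while withaferin A replicates 1 to 4 lay at 0.75, −0.01, 0.47 and 0.04.

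Several lists were called lower after celastrol with the preset correlation and not with an estimated one. Feeding neuropeptides and receptors had a median of −0.11 over 33 genes (camera adjusted p = 0.0123, and adjusted p = 0.329 with an estimated correlation). In it Oxt, the oxytocin gene, fell by 0.40 ± 0.07 (adjusted p = 0.0179); adjusted over the list alone 6 fell and 1 rose. Vgf (−0.34, adjusted p = 0.0789), Trh (−0.22, 0.128) and Sst (−0.18, 0.132), which encode other neuropeptides or their precursors, did not pass. Oligodendrocyte markers had a median of −0.16 over 17 genes (0.0021, and adjusted p = 0.151 with an estimated correlation). Opalin and Sox10 (−0.39 ± 0.08, adjusted p = 0.0433) fell, and adjusted over the list alone 7 fell and 1 rose. Immediate early genes, which neurons induce on activity, had a median of −0.15 over 22 genes (0.00345, and adjusted p = 0.375 with an estimated correlation). Npas4 fell by 0.49 ± 0.08 (adjusted p = 0.0208), and adjusted over the list alone 4 fell and 0 rose. The median of feeding neuropeptides was −0.07 without DMSO replicate 3 or celastrol replicate 3, and that of immediate early genes −0.10 without DMSO replicate 3 and −0.09 without celastrol replicate 4.

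The cholesterol synthesis list had a median of −0.14 over 19 genes after celastrol (2.03e-05, and adjusted p = 0.129 with an estimated correlation). None of these genes passed in limma, and 4 fell adjusted over the list alone. Clock genes had a median of −0.08 over 16 genes (0.0105, and adjusted p = 0.375 with an estimated correlation), with Dbp falling and 3 genes falling adjusted over the list alone. NRF2 targets had a median of −0.09 over 23 genes (0.0105, and adjusted p = 0.329 with an estimated correlation). Nqo1, an antioxidant enzyme gene of this list, fell by 0.44 ± 0.09 (adjusted p = 0.0431), and 2 genes fell adjusted over the list alone. Hypothalamic regional markers had a median of −0.13 over 19 genes (0.00204, and adjusted p = 0.219 with an estimated correlation), with 0 genes past the threshold in either count. The median of clock genes was −0.13, −0.06, −0.13 and −0.15 without DMSO replicates 3 and 4 and celastrol replicates 3 and 4, and that of hypothalamic markers −0.08 without DMSO replicate 3.

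Higher lists after celastrol were those of the IL-1 and IL-18 receptor pathway, with a median of 0.05 over 12 genes (0.0129, and adjusted p = 0.151 with an estimated correlation), and the cytosolic heat shock response, with a median of 0.06 over 19 genes (0.0123, and adjusted p = 0.36 with an estimated correlation). In both lists 0 genes passed, and adjusted over the list alone 2 rose in the former and 0 in the latter. Pituitary markers had a median of 0.33 over 7 genes (0.00204, and adjusted p = 0.219 with an estimated correlation). Their score was 1.52 on celastrol replicate 2 and between 0.02 and 0.06 on the other celastrol arrays, against −0.47 to −0.23 on the DMSO arrays, so that each celastrol array lay above each DMSO array. Gh on that array was 10.96, against 6.30 to 7.98 on all others. The median was 0.17 for pituitary markers without celastrol replicate 2, 0.04 and 0.03 for the heat shock list without DMSO replicate 3 and celastrol replicate 2, and 0.04 for the IL-1 list without celastrol replicate 4. Single arrays decided several calls: the heat shock list lost its call without DMSO replicate 3 (adjusted p = 0.225) or celastrol replicate 2 (0.108), the IL-1 list without celastrol replicate 4 (0.0777), immediate early genes without DMSO replicate 3 (0.0802) and clock genes without DMSO replicate 4 (0.0841). NRF2 targets lost it without DMSO replicate 1 (0.0639) or celastrol replicate 3 (0.0677), and feeding neuropeptides without celastrol replicate 3 (0.0677).

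The other 17 lists were not called after celastrol, with camera adjusted p from 0.0591 for thalamus markers to 0.876 for pericyte and choroid plexus markers. NF-kB targets had a camera adjusted p of 0.0619, with Nfkbia and Ptgs2 (0.85 ± 0.15, adjusted p = 0.0229) rising among 19 genes; its median of 0.02 was −0.0092 without celastrol replicate 1 and 0.065 without celastrol replicate 3. The interferon list also had 0.0619, with Ifih1 (−0.42 ± 0.09, adjusted p = 0.0433) falling among 20. Values were 0.133 for ER stress, 0.116 for proteasome subunits, 0.126 for oxidative phosphorylation and 0.587 for ribosomal proteins. Neuronal, astrocyte, microglia, endothelial and ependymal markers had values of 0.204, 0.747, 0.748, 0.326 and 0.635, and cortical, red cell and leukocyte markers 0.444, 0.326 and 0.748. For pericyte markers and for neutrophil and lymphocyte markers the median and mean were below 0 while camera gave the upward direction. Thalamus marker scores differed within each group, from −0.53 to 0.40 on DMSO arrays, −0.23 to 0.58 on celastrol arrays and −0.36 to 0.42 on withaferin A arrays.

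Among the genes fixed in advance, Lcn2 passed after celastrol and the others did not. Pomc, the precursor of the satiety peptide alpha-MSH, had a value of 0.63 ± 0.25 (adjusted p = 0.356). On the 4 celastrol arrays it lay at 8.28, 9.25, 9.34 and 8.36, and the second of these arrays is the one with high pituitary transcripts. Pomc is also abundant in the pituitary. The array with the highest Pomc, celastrol replicate 3, had a pituitary score of 0.03, above those of the DMSO arrays (−0.47 to −0.23). Gh was 6.81, 10.96, 7.98 and 7.64 on celastrol replicates 1 to 4, against 6.30 to 6.94 on the DMSO arrays. Prl on celastrol replicate 3 was 5.56, within the 5.19 to 5.90 of the DMSO arrays. Pituitary RNA as a source of the higher Pomc stays open. Npy, which stimulates feeding, had a value of −0.09 ± 0.09 (adjusted p = 0.803), Cartpt of −0.22 ± 0.09 (0.368) and the leptin receptor gene Lepr of 0.11 ± 0.09 (0.735). The astrocyte gene Gfap was at −0.05 ± 0.12 (0.931) and the chaperone gene Hspa5 at −0.03 ± 0.05 (0.883). With single arrays left out, Gfap ran from −0.12 (without celastrol replicate 4) to 0.026 (celastrol replicate 1), Npy from −0.16 (celastrol replicate 1) to −0.041 (DMSO replicate 3), Cartpt from −0.29 (celastrol replicate 4) to −0.15 (celastrol replicate 3), Lepr from 0.057 (celastrol replicate 4) to 0.15 (celastrol replicate 2) and Hspa5 from −0.053 (DMSO replicate 4) to −0.011 (DMSO replicate 1).

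Withaferin A was compared with DMSO for the same purpose. The gene with the largest positive value among the 10 of smallest p was Ide, which codes for insulin-degrading enzyme, at 0.62 ± 0.10 (SE, n = 4 per group), or 1.54-fold, with adjusted p = 0.0724. The Ide signal was 9.88, 9.87, 9.47 and 9.89 on the withaferin A arrays and between 9.04 and 9.27 on the DMSO arrays. Of its 10 nearest tested genes on the chromosome, 0 were higher by over 0.3 and 2 SE. Smaller rises escape that rule: its neighbours Btaf1 and Fgfbp3 had 0.22 ± 0.06 and 0.22 ± 0.09, each over 2 SE. Rbp4 and Fra10ac1 had −0.37 ± 0.14 and −0.23 ± 0.09. The count therefore does not show that Ide rose alone, and copy number was not measured. Snord73b had −0.63 ± 0.09 (adjusted p = 0.0627), and 2310015D24Rik, Gspt2 and Pou2f3 had 0.39, −0.49 and 0.32 (0.0724 each). Gng5, Nppa and Igsf1 had −0.46, 0.34 and −0.37 (0.0849 each), and Grifin and Nr5a2 0.41 and 0.39 (0.102 each).

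In limma's test 0 of the 14953 genes passed for withaferin A versus DMSO. At an unadjusted p under 0.05 there were 2352 genes, against 748 given by chance on average, and 8 genes had an adjusted p under 0.10. Celastrol versus DMSO had fewer genes at that unadjusted p, 1561, though 115 of them passed the threshold. Genes are not independent of one another, so such an excess over chance does not by itself show an effect. With array weights 21 genes passed, with an intensity trend and robust prior 8, and with pituitary and thalamus marker scores as covariates 9. Without DMSO replicate 3 the count was 172, with 56 higher and 116 lower, and without withaferin A replicate 3 it was 1. The genes fixed in advance did not pass. Lcn2 had a value of 0.70 ± 0.51 (95% interval −0.40 to 1.80; 0.062 without withaferin A replicate 1 and 1.06 without replicate 4), Pomc of 0.03 ± 0.25, Npy of −0.11, Cartpt of −0.22 ± 0.09, Lepr of −0.05, Socs3 of 0.09, Gfap of −0.06 and Hspa5 of −0.10 ± 0.05, with adjusted p from 0.263 to 0.968. The interval of Lcn2 rests on the pooled spread and is likely too narrow, since its SD was 1.32 with withaferin A and 0.42 with DMSO. The sign turned for Pomc without DMSO replicate 1 (−0.01) or withaferin A replicate 3 (−0.18), for Lepr without withaferin A replicate 2 (0.02) and for Gfap without withaferin A replicate 4 (0.03). Socs3 ran from 0.0018 without DMSO replicate 2 to 0.20 without DMSO replicate 3, and Npy from −0.16 without DMSO replicate 4 to −0.053 without withaferin A replicate 4.

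Camera called 11 lists after withaferin A, 2 higher and 9 lower, of which 0 were called with an estimated correlation; fry called 4. Genes of energy metabolism and translation lay lower, with oxidative phosphorylation at a median of −0.09 over 57 genes and ribosomal proteins at −0.09 over 52, each with a camera adjusted p of 7.2e-07 and adjusted p = 0.35 with an estimated correlation. Adjusted over the list alone, 7 genes of the former and 0 of the latter fell; Ndufb6 and Cox6a1 had −0.31 and −0.33, and Rpl7 and Rps29 −0.24 and −0.21. Cholesterol synthesis had a median of −0.04 over 19 genes, with 6 falling adjusted over the list alone (0.00368, and adjusted p = 0.35 with an estimated correlation), and Idi1 had −0.42 ± 0.08 (adjusted p = 0.11). Oligodendrocyte markers (median −0.13) and the heat shock list (−0.07) each had a camera adjusted p of 0.00368, NRF2 targets (−0.08) 0.00524, proteasome subunits (−0.06) 0.00583, clock genes (−0.07) 0.0101 and feeding neuropeptides (−0.07) 0.0434. With an estimated correlation their adjusted p was 0.35 for the first 3 and 0.409 for the other 3. In these 6 lists 0 genes passed in limma, and adjusted over the list alone 1, 0, 2, 0, 2 and 2 genes fell. The median of cholesterol synthesis was −0.09 without withaferin A replicate 2 and −0.08 without replicate 4, that of proteasome subunits −0.03 without DMSO replicate 1, and that of clock genes −0.02 without DMSO replicate 4 and −0.03 without withaferin A replicate 1.

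The glucocorticoid-responsive list had a median of 0.31 after withaferin A, with 0 of 23 genes past the threshold and 8 rising adjusted over the list alone (7.2e-07, and adjusted p = 0.405 with an estimated correlation). Zbtb16 and Fkbp5 in it had values of 0.86 ± 0.30 (adjusted p = 0.228) and 0.59 (0.259). The list mean over DMSO was 0.75, −0.01, 0.47 and 0.04 on the 4 arrays, and the median change was 0.19 without withaferin A replicate 1. NF-kB targets had a median of 0.08 over 19 genes (0.0261, and adjusted p = 0.35 with an estimated correlation), and 0 passed in either count; the median was 0.04 without DMSO replicate 1 or withaferin A replicate 4 and 0.12 without DMSO replicate 3. The STAT3 list had a median of 0.05 and a camera adjusted p of 0.111. Calls were lost without 1 array for NF-kB targets (without withaferin A replicate 1, adjusted p = 0.0525), for feeding neuropeptides (without DMSO replicate 3, 0.203, withaferin A replicate 2, 0.0834, or withaferin A replicate 4, 0.146) and for clock genes (without DMSO replicate 4, 0.0682, or withaferin A replicate 2, 0.0503). The other 17 lists were not called, with pituitary markers at 0.0765 and thalamus markers at 0.187. Median and mean had opposite signs for interferon genes and ependymal markers, and both were below 0 for pericyte markers, for which camera gave the upward direction.

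The compounds were then compared with each other, at doses that differ (100 µg/kg of celastrol and 2 mg/kg of withaferin A). Ide was higher with withaferin A than with celastrol by 0.73 ± 0.10 (SE, n = 4 per group), or 1.65-fold. Ch25h was lower with withaferin A by a log2 value of −1.34 ± 0.20, or 2.53-fold. Txnip, a thioredoxin inhibitor gene induced by glucose, was lower by −0.70 ± 0.09, and Zfp36, whose product destabilises cytokine transcripts, by −0.51 ± 0.07. Srarp, Ppil6 and Podxl were lower by −0.58 ± 0.08, −0.54 ± 0.08 and −0.45 ± 0.07. For these lower genes the withaferin A mean lay near the DMSO mean, with the celastrol mean above both. With DMSO, celastrol and withaferin A, the means were 5.79, 7.22 and 5.88 for Ch25h and 8.64, 9.45 and 8.75 for Txnip. They were 6.37, 6.84 and 6.34 for Zfp36 and 6.005, 6.55 and 5.97 for Srarp. Ppil6 had 7.57, 8.02 and 7.48, and Podxl 9.01, 9.36 and 8.92.

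These 7 genes, 1 higher and 6 lower with withaferin A, were those past the threshold in limma, with adjusted p from 0.0231 to 0.0306; at an unadjusted p under 0.05 there were 2413. Cenpc1, Fn1 and Lrg1 followed at −0.39, −0.78 and −0.96 (0.0632 each). Lcn2 differed by −2.74 ± 0.51 (95% interval −3.84 to −1.65, adjusted p = 0.0713) and Zbtb16 by −0.98 ± 0.30 (−1.63 to −0.32, adjusted p = 0.182), so neither passed. Both SE and intervals rest on the spread pooled over the 3 groups and are likely too narrow here. The SD with withaferin A was 1.32 for Lcn2 and 0.87 for Zbtb16, against 0.63 and 0.21 with celastrol and 0.42 and 0.13 with DMSO. The count was 1, 0 and 15 without celastrol replicates 2, 3 and 4, 56, 1 and 0 without withaferin A replicates 1, 2 and 4, and 17 without both celastrol replicate 2 and withaferin A replicate 1, a choice made after the data were seen. With the 8 arrays of both groups alone, and with pituitary and thalamus marker scores as covariates, the count was 0.

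Camera called 7 lists for the difference, 6 lower and 1 higher with withaferin A, and 0 of them with an estimated correlation. Fry called 2, the STAT3 list (fry adjusted p = 0.00315) and the heat shock list (0.0116). The glucocorticoid-responsive list was lower by a median of −0.42 (2.38e-14, and adjusted p = 0.313 with an estimated correlation), with 17 of 23 genes lower adjusted over the list alone and 0 over all genes. The STAT3 list was lower by a median of −0.15 (1.57e-05, and adjusted p = 0.0516 with an estimated correlation), with Ch25h past the threshold and 7 genes lower adjusted over the list alone. Without members shared with the glucocorticoid-responsive list it had a median of −0.07 and adjusted p = 0.046 with an estimated correlation, a form chosen after the data were seen; the median of the full list was −0.09 without withaferin A replicate 2. Heat shock genes differed by a median of −0.11 (5.09e-07, and adjusted p = 0.166 with an estimated correlation), with Hspe1 at −0.31 (adjusted p = 0.0949), Chordc1 at −0.45 (0.112) and 5 genes lower adjusted over the list alone. Ribosomal proteins (median −0.07, 1.5e-05), oxidative phosphorylation (−0.05, 0.000195) and ER stress (−0.06, 0.0304) each had adjusted p = 0.515 with an estimated correlation. Immediate early genes were higher by a median of 0.11 (0.0229, and adjusted p = 0.806 with an estimated correlation). Calls were lost for ER stress genes without celastrol replicate 1 (adjusted p = 0.051), celastrol replicate 3 (0.195), withaferin A replicate 3 (0.0718) or withaferin A replicate 4 (0.0751), and for immediate early genes without celastrol replicate 1 (0.0638), withaferin A replicate 3 (0.0562) or withaferin A replicate 4 (0.0501). Median and mean had opposite signs for NRF2 targets, clock genes and neuronal, microglia, endothelial and pericyte markers, which were not called.

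Of the 115 genes that changed after celastrol, 109 had the same sign after withaferin A. Their median absolute log2 change was 0.49 after celastrol, and the median change after withaferin A in the direction of celastrol was 0.22. These genes were selected on the celastrol values, and both comparisons share the DMSO arrays, which alone favours equal signs. With 2 DMSO arrays for picking 115 genes on celastrol and the other 2 for withaferin A, a form chosen after the data were seen, 92 to 107 of 115 had the same sign over the 6 assignments, with medians of 0.17 to 0.23. The mean of the 68 genes that rose was 0.56, 0.10, 0.36 and 0.06 above DMSO on withaferin A replicates 1 to 4, against 0.71 to 0.81 on the celastrol arrays. Across all genes, which are not independent replicates, the changes of the compounds had a Pearson r of 0.430 and a Spearman rho of 0.399. Simulated groups without effects gave a mean r of 0.498 from the shared controls alone. The simulated errors were independent between genes, so the simulation cannot show how far r varies with correlated genes. It therefore does not decide whether the compounds agree beyond the shared controls. With the controls split 2 and 2, r was 0.174 on average, between −0.07 and 0.37. The covariance was 0.0073, against 0.0038 in the simulation and 0.0030 on average with the controls split (−0.0019 to 0.0065). At an adjusted p of 0.05 the compounds shared 0 genes, and at 0.10 they shared 2310015D24Rik, which rose with both, and Igsf1, which fell with both.

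**Figure D3:**
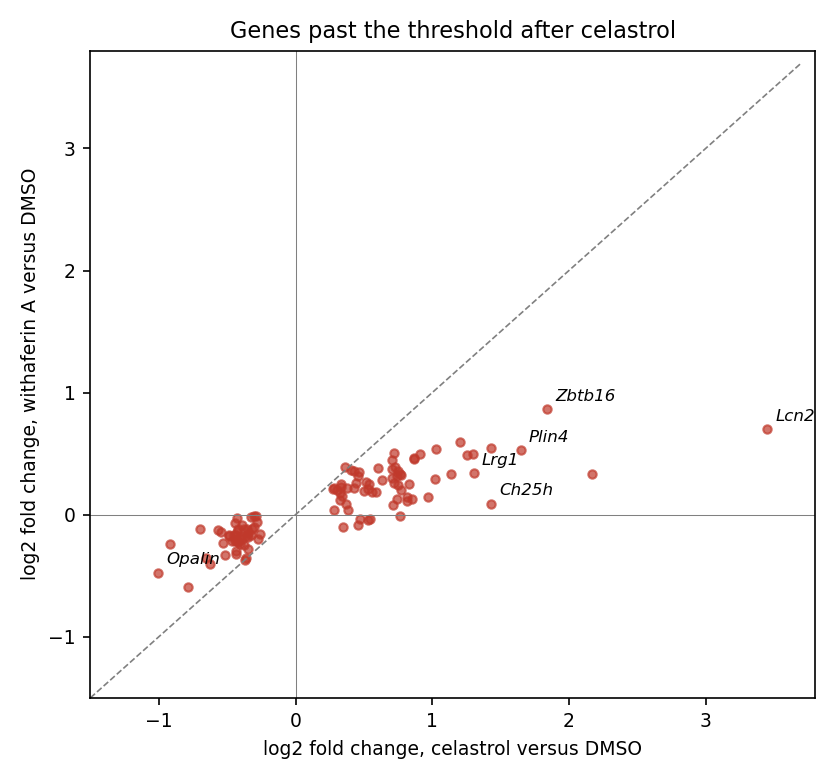
Log2 fold change versus DMSO after celastrol (horizontal axis) and after withaferin A (vertical axis) of the 115 genes past the threshold after celastrol, 1 point per gene, with 6 genes named and a dashed line where both are equal. Of these genes 109 had the same sign with both compounds, and Lcn2 lay at 3.45 and 0.70.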

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

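The test with pituitary and thalamus scores the value given for glucocorticoid receptor activity and the counts of genes nearer to another group on withaferin A replicate 1 were chosen only after the result was seen. Signals far from the rest of their group were sought in 219 groups of 4 arrays, over 44 genes and 29 list scores. Chance marks about 1 in 20 groups, or 10.9 of these, and 9 were found.

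The pattern a biologist would first follow is the higher glucocorticoid-responsive list with celastrol. The 35 splits of the 8 arrays into 4 and 4 gave at most 0 genes beyond the real split with 115. This argues against chance for that count but cannot exclude it, since 1 split as large is the fewest possible. RNA from pituitary or thalamus is argued against as the whole cause, though pituitary scores of celastrol (0.02 to 1.52) and DMSO arrays (−0.47 to −0.23) did not overlap, so that the fit extrapolates: withaferin A replicates 2 and 3, with scores of 0.05 and 0.02 like 3 of the celastrol arrays, had list means of −0.01 and 0.47, against 0.78 to 0.91 with celastrol, and with both marker scores as covariates the list mean was 0.89 ± 0.24, against 0.86 ± 0.15 without; as the error widened, genes past the threshold went from 115 to 0, list members past it from 15 to 0, and the list's adjusted p with an estimated correlation from 0.0388 to 0.156. A shift in clock time stays open: Arntl, Clock and Cry1 had a mean of 0.05 ± 0.06 while Dbp, Per2, Per3, Nr1d1 and Nr1d2 had −0.33 ± 0.04. A mean of the former below its error was the outcome set beforehand against a shift, but a small opposite change lies within that error. More glucocorticoid receptor activity could account for the list but was not tested apart from it, since the list's own adjusted p of 0.0388 with an estimated correlation prompted the idea, corticosterone and food intake are not used here, and fasting induces many of the same genes.

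The mean of the glucocorticoid-responsive list differed more among the withaferin A arrays (SD 0.36, n = 4) than among the DMSO (0.10) or celastrol arrays (0.06). For withaferin A versus DMSO the real split called 0 genes and the highest other split 72; all 35 splits are as large as a count of 0 by construction, which says nothing about chance, and the split with 72 exchanges DMSO replicate 3 and withaferin A replicate 3, which points to a structure of the samples. A celastrol sample under the label of withaferin A replicate 1 stays open, since the tests point both ways. On 50 genes, from 0 at celastrol to 1 at the other withaferin A arrays, it lay at 0.663, above held-out celastrol arrays at 0.504, 0.0628, 0.404 and 0.210. That was the outcome set beforehand against such a label, but by less than their spread. DMSO arrays lay at −0.343, 0.219, 0.622 and 0.139, so a high position is not particular to withaferin A. With each celastrol array held out in turn, 25, 15, 22 and 23 of 50 genes separating these groups lay nearer to withaferin A on withaferin A replicate 1. The held-out celastrol arrays had 14, 5, 6 and 15. All 7 genes called between the compounds, a call withaferin A replicate 1 took part in, lay outside the celastrol range on it, with Txnip at 8.81 against 9.42 to 9.50 and Ide at 9.88 against 8.97 to 9.21. Yet of 50 genes separating celastrol from DMSO only 4 to 9 lay nearer to DMSO on it, within the 2 to 11 of held-out celastrol arrays. Exchanged labels of DMSO replicate 3 and withaferin A replicate 3 also stay open: from 0 at DMSO to 1 at withaferin A they lay at 0.533 and 0.488. These are the sides of the midpoint set beforehand for exchanged labels, but both lie close to it. They fell between the held-out DMSO arrays (at most 0.249) and withaferin A arrays (at least 0.596), and Ide was 9.04 and 9.47 on them. No biological explanation was tested.

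Ide was higher with withaferin A, with replicate 3 at 9.47 far below the other 3 arrays of its group at 9.87 to 9.89. For withaferin A versus celastrol, where Ide passed, the real split called 7 genes and the highest other split 1, each fitted with all 12 arrays. With 1 of 35 splits as large, the fewest possible, this argues against chance for that count but cannot exclude it. With the 8 arrays of both compounds alone, 0 genes passed and Ide lost its call. An unbroken copy number gain reaching the genes on either side of Ide is argued against, since Marchf5 and Exoc6 had −0.12 ± 0.07 and −0.09 ± 0.08. By the rule set beforehand, 0 of the 10 nearest tested genes were higher by over 0.3 and 2 SE, but that rule could not see smaller rises. Btaf1 and Fgfbp3, named after their values were seen, were at 0.22 ± 0.06 and 0.22 ± 0.09 (adjusted p = 0.182 and 0.278), each over 2 SE. A copy change of Ide alone, a rearranged segment holding Ide with some of its neighbours and an effect of withaferin A could each account for the higher Ide. All of these stay open, since copy number was not measured.

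Socs3 on withaferin A replicate 3 was 7.37, below the other arrays of its group at 7.59 to 7.63. The pituitary score was 1.52 on celastrol replicate 2, against 0.02 to 0.06 on the other celastrol arrays and −0.47 to −0.23 on the DMSO arrays, and 5 of 7 pituitary markers were highest there. The score of feeding neuropeptides was 0.079 on DMSO replicate 3, above 0.03 to 0.04 on the others. The STAT3 score was −0.0064 on DMSO replicate 1, above −0.21 to −0.18. The ER stress score was −0.051 on withaferin A replicate 4, with the others at −0.02. The microglia score was 0.10 on DMSO replicate 4, above 0.00 to 0.01. The endothelial score was −0.14 on withaferin A replicate 1, below 0.03 to 0.05. The choroid plexus score was −0.18 on celastrol replicate 4, below 0.02 to 0.04. Among probe sets without a gene name, outside the comparisons per gene, probe set 10339371 was higher with celastrol by 1.37, or 2.59-fold (adjusted p = 0.0337 over all probe sets).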

How the results depend on the processing

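The pituitary and thalamus scores as covariates and the omission of celastrol replicate 2 with withaferin A replicate 1 were chosen after the data were seen. Over the alternatives signs seldom turned, but calls were often lost. Single genes stayed on the same side of the threshold in 1069 cases, lost their call in 170, gained one in 55 and turned sign in 7. Gene lists, by the direction of the test, did so in 675, 74, 45 and 4. The cases that stayed include genes and lists not called in the main fit. Among called genes, Sgk3 after celastrol lost its call in 15 of 24 alternatives and Plin4 in 12 of 24. Ch25h between the compounds lost it in 11 of 23. Dbp, Lrg1 (23 or 24 alternatives), the glucocorticoid-responsive list and the STAT3 list (19 each) kept their calls after celastrol in the alternatives run, except that with the pituitary and thalamus scores together Dbp and Lrg1 lost theirs, and the 2 lists had adjusted p of 0.156 and 0.0982 with an estimated correlation (1.18e-24 and 0.000111 with the preset one). Counts depended on the settings. After celastrol (115) they were 60 without a filter, 5 with every probe set, 195 with an intensity trend and robust prior, 219 with array weights, 182 with the arrays of the 2 groups alone, 54 with a replicate block, 212 at 0.10 and 0 with the pituitary and thalamus scores together, and from 6 to 207 with 1 array left out. The calls shared with the 115 numbered 53 without a filter and 53 with the block. For withaferin A (0) the counts were 8 with the trend, 21 with weights, 8 at 0.10, 4 with the thalamus score, 9 with both scores and 0 to 172 with 1 array left out. For withaferin A versus celastrol (7) they were 11 without a filter, 13 with a filter at the 50th percentile, 0 with every probe set, 29 with the trend, 19 with weights, 0 with 2 groups alone, 77 at 0.10, 17 without the 2 arrays, 0 with both scores and 0 to 56 with 1 array left out. Every probe set means more tests, but the prior of the fit was then also estimated anew, and the effects of these were not separated. The 2 scores widened the errors after celastrol. Elsewhere the cause was not tested. The replicate numbers did not pair the arrays: deviations of the 12 pairs with equal numbers correlated from −0.28 to 0.12. The correlation of the compounds was 0.174 with the controls split, which removes the shared arrays, and their overlap was 2 at 0.10. Signs turned for values near 0: with withaferin A, Pomc went to −0.020 with the thalamus score and ran from −0.18 to 0.14 with 1 array left out, Gfap from −0.15 to 0.025, Lepr from −0.12 to 0.018, immediate early genes from −0.083 to 0.034, and thalamus markers went to −0.045 with their own score as covariate; with celastrol, Gfap ran from −0.12 to 0.026, the median of NF-kB targets from −0.0092 to 0.065, and that of thalamus markers went to −0.035 with their own score. Renewed scaling moved the median of all genes by at most 0.02. Genes with a log2 signal under 5.81 were not tested, and small changes of dim genes stay undetected.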

Other observations

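The genes described here were chosen only after the result was seen. Of 16 endothelial markers 1 rose and 1 fell after celastrol. Slc2a1, the glucose transporter gene of the blood-brain barrier, rose by 0.75 ± 0.15 (adjusted p = 0.0384), and Tek, an angiopoietin receptor gene, fell by 0.55 ± 0.11 (0.045). Adjusted over the list alone, 3 of 16 rose and 6 fell, among them Vwf at 0.48 ± 0.11, Kdr at −0.63 ± 0.15 and Slco1c1, a thyroid hormone transporter gene, at −0.56 ± 0.13. Camera did not call the list (adjusted p = 0.326).

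In the astrocyte and microglia lists 0 genes passed over all genes tested after celastrol. Among astrocyte markers, Gjb6 had 0.43 ± 0.10 (adjusted p = 0.0698) and Sox9 −0.37 ± 0.08 (0.063), with 1 rising and 1 falling adjusted over the list alone. Among microglia and macrophage markers, C1qb and Ctss had 0.33 ± 0.09 and 0.16 ± 0.05, and P2ry12 and Trem2 −0.34 ± 0.12 and −0.20 ± 0.06, with 2 rising and 2 falling adjusted over the list alone. Of 15 ependymal and tanycyte markers 3 had a positive value (median −0.07). Dio2, which activates thyroid hormone, and Crym had 0.50 ± 0.12 (adjusted p = 0.0922) and 0.40 ± 0.11 (0.127), the 2 that rose adjusted over that list alone, while Rax and Nes had −0.30 ± 0.16 (0.559) and −0.38 ± 0.18 (0.484). Gad1, Gad2 and Slc32a1, genes of GABA synthesis and transport, had −0.20, −0.20 and −0.23, the 3 members of the neuronal list that fell adjusted over the list alone.

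Cga and Prl were also highest on celastrol replicate 2, at 10.39 and 9.80. Cga lay between 6.39 and 9.15 elsewhere and Prl at up to 6.08. Scgb3a1, outside the rule for named genes, rose by 2.17 with celastrol.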
